A study of Mus musculus with 6 samples.

How the data were processed

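Total RNA of 6 cultures of mouse bone marrow mesenchymal stromal cells was labelled with biotin and hybridised to Affymetrix arrays, per the labels. Ploidy had been assigned by flow cytometry of DNA content and by spectral karyotyping, per the labels' protocols. The groups were 3 tetraploid and 3 diploid samples, as the titles give them, and the descriptions gave the origin of each sample as a primary culture or as a line or clone.

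The deposited value table held log2 expression per probe set after RMA, which corrects background, normalises probes across arrays and summarises them, and the submitters' processing notes name RMA and Partek without versions. The unit was checked against the values, which ran from 2.73 to 14.1. The authors' deposited comparison table held an unadjusted p-value and a signed fold of diploid over tetraploid for each of 35399 probe sets, per the file headers. Its log2 folds equalled the differences of the deposited values to within 7.9e-05, and its p-values equalled those of an ordinary linear model to within 0.00047. That table also held 6 columns of per-sample values whose names matched no sample label, and these were not used here. The genome build was not given in the sources used here, so no coordinates are printed.

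Probe sets were named by the symbols of the authors' deposited table. Of 35399 probe sets, 25917 had 1 symbol, 0 had several and 9482 had none. Symbols were updated through a RefSeq gene table of assembly GRCm38.p6. Of 22349 symbols, 19017 were current, 2383 were matched as a synonym and 949 kept the name in the file. The same table gave the order of genes around H19. A gene was represented by its probe set with the highest mean over the 6 arrays, which left 22311 genes, 1988 of them with several probe sets. There were 340 named probe sets with the same values as another named probe set.

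The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, tetraploid minus diploid, over all 6 arrays without covariates, two-sided, with Benjamini-Hochberg adjustment and no filter on dim probe sets. A looser count used an unadjusted p under 0.05 and a 2-fold difference. The ploidy difference within each origin and the difference between origins were fitted in a limma model with 1 mean per ploidy and origin. H19 also had an exact permutation test, which with 3 samples against 3 cannot give a p under 0.1. The p-values measure the spread between these cultures.

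The 28 gene lists were fixed before the data were examined, and 790 of their 793 genes were measured. Lists were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. None of the 7 calls held with an estimated correlation. Of fry tests, which ask whether a list's genes move on balance one way without a comparison with other genes, 0 passed. The named genes were H19, up to 12 genes per direction past the adjusted threshold filled up to 10 with genes of unadjusted p under 0.01 and no overlap between the groups, the 3 genes of each list with the smallest unadjusted p, and Xist with 4 Y-linked genes. No gene passed the adjusted threshold, so each direction was filled by the looser rule. The neighbours of H19, Cdh5 and Flt1 in the report, and the genes named as values of single samples, were chosen after their values were seen.

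The alternatives were quantile normalisation of the deposited values, centring of the arrays, a filter on dim probe sets, other variance models, array weights, the repeat number as a block, origin as a covariate, leaving out each replicate, all probe sets, the mean of a gene's probe sets, other list tests, a 1.5-fold threshold and the authors' deposited values. Leaving out tetraploid II together with diploid III, and an estimated correlation within lists under the other normalisations, models and sets of replicates, were added after seeing the data. The limma and camera steps were tested on simulated data for 22311 genes. With no change, 0 genes were called and 5.06% had an unadjusted p under 0.05. Of 50 genes each, changed by 1, 2, 4 and 5 on the log2 scale, 12%, 66%, 86% and 94% were called at an adjusted p under 0.05 (limma). All these genes were changed in the same simulation. In the real data H19, with a log2 difference of -5.17, was not called (limma, adjusted p = 0.876). The simulated shares therefore cannot be taken as the power of the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.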

Results

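Expression was measured on Affymetrix arrays in 6 cultures of mouse bone marrow mesenchymal stromal cells, the adherent cells of the marrow that can form bone, fat and cartilage. There were 3 tetraploid samples and 3 diploid samples, 1 array each. Tetraploid I was a primary culture, tetraploid II a cell line and tetraploid III a clone made tetraploid artificially, while diploid I was a clone and diploid II and III were primary cultures. The array medians lay between 4.54 and 4.78 on the log2 scale. The interquartile range was 2.75 in diploid III and between 3.16 and 3.24 on the other 5 arrays. Tetraploid II was the array with Y-linked expression, with Ddx3y at 9.80, Eif2s3y at 8.69, Uty at 8.01 and Kdm5d at 6.54, and its Xist value was 3.68. On the other 5 arrays Xist lay between 9.71 and 11.04 and Ddx3y between 3.88 and 4.23. The number of arrays limits the precision of every comparison, and the labels do not say whether the cultures came from separate animals or whether the artificial tetraploid clone was made from one of the diploid samples.

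The first question, named by the study's title, was whether the imprinted non-coding RNA H19 is expressed at a lower level in polyploid cells. H19 was near the lower end of the scale in each tetraploid sample, at 3.92, 3.97 and 3.75, and far above it in each diploid sample, at 8.36, 10.46 and 8.33. The means were 3.88 ± 0.11 (SD, n = 3) and 9.05 ± 1.22 (SD, n = 3). The log2 difference, tetraploid minus diploid, was -5.17 (SE 0.61), with a measured ratio of 36.0-fold. The size of that ratio is uncertain, because the tetraploid values lay close to the arrays' lower quartiles (3.82 to 4.02). The probe set was 10569335, and the other H19 probe set, 10569341, had a log2 difference of -3.33 (SE 0.52), a ratio of 10.1-fold. Igf2, the growth factor gene next to H19 that is imprinted in the opposite parental direction, had a log2 difference of 0.31 (SE 0.67). Diploid II (6.75) lay above all tetraploid values of Igf2 (4.98 to 6.30), and diploid I and III (4.63 and 4.74) lay below them. Mrpl23, the mitochondrial ribosomal protein gene on the other side of H19, differed by -0.45 (SE 0.37), and Ctsd, a lysosomal protease gene nearby, by -0.51 (SE 0.19). For Mrpl23, diploid III (8.97) lay within the tetraploid range (8.67 to 9.51) and diploid I and II (10.08 and 9.84) above it. Ifitm10, 8 measured genes away, differed by -1.02 (SE 0.12) at a low level, with means of 3.77 and 4.79, and was picked out after its values were seen.

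H19 did not pass the threshold over all probe sets (limma, Benjamini-Hochberg adjusted p = 0.876), and without diploid II its adjusted p was 0.0208 at a log2 difference of -4.46. It was the 1 gene of the imprinted list to pass when adjusted over the list alone (limma, adjusted p = 0.00762). The study named H19 from these samples, so this is not independent evidence. An exact two-sided permutation test gave p = 0.1 for each probe set, the smallest p that 3 samples against 3 can give. In the authors' deposited table, whose folds run in the opposite direction, diploid over tetraploid, H19 had folds of 36.0 and 10.1.

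**Figure D1:**
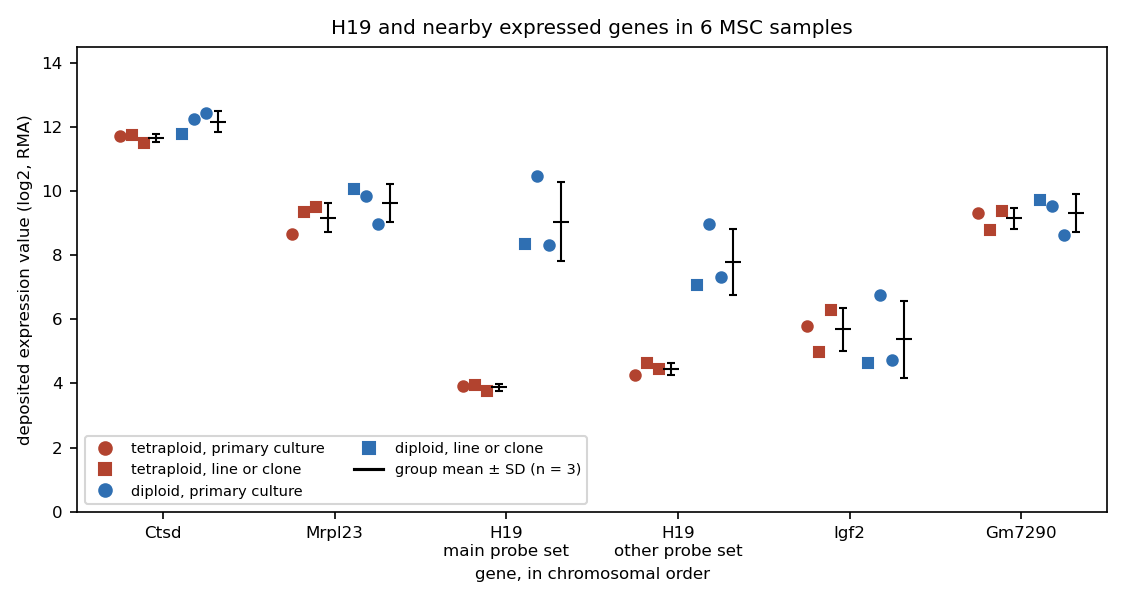
Deposited log2 expression values of H19 and of 4 nearby expressed genes in the 6 samples, in chromosomal order, with circles for primary cultures, squares for lines or clones, and group means with SD as horizontal and vertical bars. The tetraploid values of the main H19 probe set lie between 3.75 and 3.97 and the diploid values between 8.33 and 10.46, while the groups overlap for Igf2 and Mrpl23.

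The second question was which other genes differed with ploidy. Rspo2, a secreted enhancer of Wnt signalling, was higher by 4.37 on the log2 scale (SE 1.02), with 10.48 ± 1.12 in the tetraploid samples and 6.11 ± 1.76 in the diploid samples (SD, n = 3 each), and by 2.76 without both tetraploid II and diploid III. F3, the tissue factor that starts coagulation, was higher by 3.27 (SE 0.80), and Vegfd, a growth factor for lymphatic vessels, by 3.12 (SE 0.76). Among genes of secreted matrix proteins, Aspn was higher by 2.74 (SE 0.31), Col6a3 by 2.23 (SE 0.34) and Col12a1 by 1.94 (SE 0.39). Olfml3 and Srpx2, which encode secreted glycoproteins, were higher by 3.20 (SE 0.77) and 2.89 (SE 0.37). Galnt18 and Csgalnact1, which encode enzymes that add sugars to proteins and proteoglycans, were higher by 2.15 (SE 0.40) and 1.99 (SE 0.51).

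Among genes with no overlap between the groups and an unadjusted p under 0.01, the largest negative difference after H19 was that of Bmper, which encodes a binding protein of bone morphogenetic proteins. Its log2 difference was -3.46 (SE 0.45), with 5.75 ± 0.90 in the tetraploid samples and 9.22 ± 0.16 in the diploid samples (SD, n = 3 each). The mitotic kinase gene Plk1 differed by -1.51 (SE 0.27) and the proliferation marker Mki67 by -1.06 (SE 0.21). Plin2, which encodes a coat protein of lipid droplets, differed by -1.50 (SE 0.38). Limk1, which encodes a kinase that regulates actin, and Ezr, which encodes ezrin, a link between the membrane and actin, both differed by -1.26 (SE 0.31 and 0.32). Prag1 differed by -1.16 (SE 0.30), and Ivns1abp by -1.32 (SE 0.28) at 1 probe set and by -0.17 (SE 0.17) at its other, dimmer probe set. The histone gene H4c17 differed by -1.56 (SE 0.39), a value that is uncertain because histone paralogs have near-identical sequences.

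None of these genes passed the adjusted threshold. The tetraploid mean of H19 and the diploid means of Srpx2 (4.44) and Aspn (4.38) lay below the median of every array, so the sizes of their differences are uncertain. Of 25917 probe sets tested, 0 had an adjusted p under 0.05 (limma, Benjamini-Hochberg, smallest adjusted p = 0.876), and 1332 had an unadjusted p under 0.05, against 1296 given by chance. The ordinary linear model of the authors' deposited table also gave 0 after adjustment, with 1124 unadjusted. At an unadjusted p under 0.05 and a 2-fold difference there were 284 probe sets, 180 higher and 104 lower in the tetraploid samples. The total was 166 without tetraploid II and 636 without tetraploid III, and the balance turned to 163 higher and 211 lower without diploid III and to 210 and 225 with array weights. The 3 values of one group lay wholly above the 3 of the other in 12.1% of probe sets, where chance gives 10%.

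**Figure D2:**
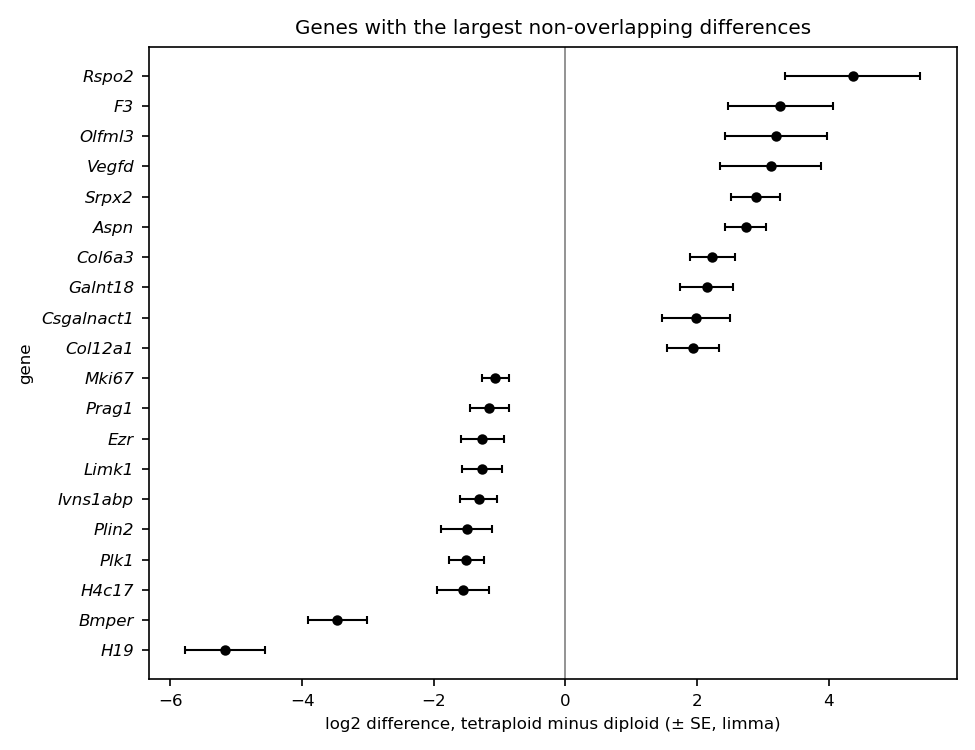
Log2 differences, tetraploid minus diploid, of the 10 genes per direction with the largest non-overlapping difference at an unadjusted p under 0.01, shown as points with limma standard errors as bars. Rspo2 has the largest positive difference, 4.37, and H19 the largest negative one, -5.17; no gene shown passed the adjusted threshold.

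Genes of mitosis and the spindle were lower in the tetraploid samples as a group. Of 50 measured genes, 49 had a lower mean in the tetraploid samples, 15 of them at an unadjusted p under 0.05, with a median log2 difference of -0.73 (limma camera, adjusted p = 1.2e-15; adjusted p = 0.673 with an estimated correlation). Plk1, Mki67 and Ndc80, a kinetochore gene at -0.68 (SE 0.15), had the smallest p-values of the list. The list means were 6.29, 5.57 and 6.01 in tetraploid I to III and 7.27, 6.66 and 6.23 in diploid I to III, so that the groups overlapped. Without diploid I the median was -0.47. Of 45 DNA replication genes, 38 were lower, 7 at an unadjusted p under 0.05, with a median of -0.25 (camera, adjusted p = 0.000198; adjusted p = 0.803 with an estimated correlation). Pole and Pold1, which encode subunits of replicative DNA polymerases, differed by -0.82 (SE 0.17) and -0.58 (SE 0.19). Without diploid II the replication list did not pass (camera, adjusted p = 0.172, median -0.17).

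Genes of cholesterol synthesis were higher, and genes of glycolysis and the hypoxia response lower, in 2 of the 3 tetraploid samples. All 25 cholesterol synthesis genes had a higher mean in the tetraploid samples, 1 of them at an unadjusted p under 0.05, with a median of 1.08 (camera, adjusted p = 7.6e-14; adjusted p = 0.673 with an estimated correlation). The list mean was 8.87 in tetraploid I, 8.81 in tetraploid II and 7.14 in tetraploid III, against 7.08 to 7.19 in the diploid samples. Sc5d, Sqle and Lss, which encode enzymes of the sterol pathway, were higher by 1.43 (SE 0.41), 1.68 (SE 0.69) and 1.56 (SE 0.64). Without tetraploid III, the tetraploid sample without the higher values, the median of the list was 1.72 (camera, adjusted p = 0.0272 with an estimated correlation). Leaving out the sample that lacks the pattern favours such a call. An estimated correlation in that setting was also added after seeing the data, with no adjustment over settings. The call is therefore not evidence for the list. Of 31 glycolysis and hypoxia genes, 27 were lower, 4 at an unadjusted p under 0.05, with a median of -0.47 (camera, adjusted p = 0.000307; adjusted p = 0.673 with an estimated correlation). Their list mean was 8.76 in tetraploid I, 8.71 in tetraploid II and 9.57 in tetraploid III, against 9.64 to 9.68 in the diploid samples. Egln3, an oxygen sensor gene, differed by -3.13 (SE 0.95), and the glycolytic genes Gpi1 and Pfkp by -0.97 (SE 0.26) and -1.16 (SE 0.39).

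Extracellular matrix genes were higher in the tetraploid samples as a group. Of 46 genes, 34 were higher, 6 at an unadjusted p under 0.05, and 12 were lower, 1 at that p, with a median of 0.44 (camera, adjusted p = 4.6e-05; adjusted p = 0.215 with an estimated correlation). The list means were 9.05 to 9.38 in the tetraploid samples and 8.41 to 8.65 in the diploid samples. Col6a3 passed when adjusted over the list alone (limma, adjusted p = 0.0383), with no adjustment across the lists. Mfap5, a microfibril gene, had 8.77 ± 2.48 in the tetraploid samples and 4.18 ± 0.10 in the diploid samples (SD, n = 3 each), where it lay below the median of every array, so the size of its difference is uncertain. The median of the list was 0.22 without diploid II.

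Tetraploid I had the highest value for 29 of 34 interferon response genes. Of these 34 interferon genes, 27 had a higher mean in the tetraploid samples, 0 of them at an unadjusted p under 0.05, and of the 7 lower genes 1 was at that p, with a median of 0.40 (camera, adjusted p = 0.0273; adjusted p = 0.803 with an estimated correlation). The list mean was 7.57 in tetraploid I and 5.10 to 6.02 in the other samples, and without tetraploid I the median was -0.30 and the list passed in the opposite direction (camera, adjusted p = 0.00286; adjusted p = 0.923 with an estimated correlation). The median was 0.89, 0.84 and 0.76 without tetraploid II, tetraploid III and diploid III, and 0.81 with array weights and 0.995 with origin as a covariate. Without diploid I or without diploid II the median fell to 0.24 and 0.27 and the list did not pass (camera, adjusted p = 0.218 and 0.0732). The interferon list also failed after quantile normalisation (camera, adjusted p = 0.0871) and with the filter on dim probe sets (0.223). Of 20 endothelial markers, 16 were lower, 1 at an unadjusted p under 0.05, with a median of -0.17 (camera, adjusted p = 0.0484; adjusted p = 0.803 with an estimated correlation). Diploid III, the array with the narrower value range, had the highest value for 14 of these 20 markers, and also for 20 of 30 myeloid, 15 of 20 lymphocyte, 10 of 16 erythroid and megakaryocyte and 13 of 20 epithelial markers. Ets1, a transcription factor gene, differed by -0.67 (SE 0.17). Cdh5, the endothelial cadherin gene, had 11.03 in diploid III and 3.70 to 3.79 in the other samples, and Flt1, a receptor gene for vascular growth factors, had 7.32 in diploid III and 3.89 to 4.44 in the others. Without diploid III the endothelial list did not pass (camera, adjusted p = 0.482, median -0.053), nor without tetraploid III (0.217), after quantile normalisation (0.166), with array weights (0.276) or with origin as a covariate (0.107). With the filter on dim probe sets its median was -1.14.

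**Figure D3:**
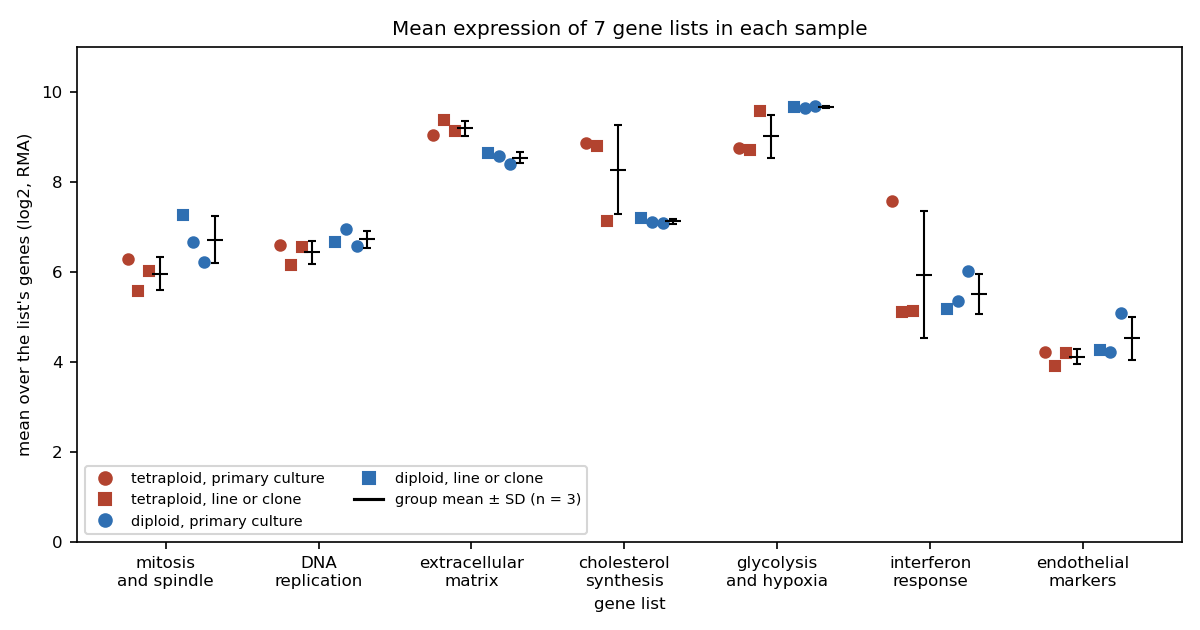
Mean log2 expression over the genes of the 7 gene lists that camera called with its preset correlation, per sample, with circles for primary cultures, squares for lines or clones, and group means with SD. Tetraploid III lies at 7.14 for cholesterol synthesis, next to the diploid samples at 7.08 to 7.19, and tetraploid I lies at 7.57 for the interferon response, above all other samples.

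The other 21 lists did not pass (camera, smallest adjusted p = 0.125), but 7 of them passed under an alternative with the preset correlation. None of these calls held in the same setting with an estimated correlation (camera, smallest adjusted p = 0.208). Without tetraploid II the p53 targets passed with a median of 0.55, the cell cycle inhibitors with 0.18 and the smooth muscle genes with 0.19. Oxidative phosphorylation genes passed without diploid I (median 0.18), lymphocyte genes without diploid II (-0.14), osteoblast genes with the filter on dim probe sets (0.65), and NRF2 and glutathione genes in 7 alternatives. The medians of all 21 lists moved by over 1.5 times or turned sign when 1 replicate was left out. Among regulators of growth, the 32 p53 target genes had a median of 0.11, the 20 cell cycle inhibitors -0.0029, the 25 centrosome genes 0.014, the 25 senescence secretory genes -0.28 and the 18 insulin-like growth factor genes 0.24. Gas1, a growth arrest gene, was higher by 1.86 (SE 0.45), and Tob1, an antiproliferative gene, by 0.73 (SE 0.21). The 36 imprinted genes had a median of 0.025. Among lineage lists, the 24 stromal markers had a median of 0.13, the 26 osteoblast genes -0.0086, the 30 adipocyte genes -0.027, the 23 chondrocyte genes -0.052, the 25 smooth muscle genes 0.014 and the 25 skeletal muscle genes -0.063. Cxcl12, the chemokine gene of the marrow niche, was higher by 1.79 (SE 0.64), and Lpl, the lipoprotein lipase gene, by 3.51 (SE 1.27), and by 2.17 without tetraploid II. Among pathways, the 41 oxidative phosphorylation genes had a median of 0.059, the 25 NRF2 and glutathione genes -0.41, the 24 TGF-beta genes -0.31, the 30 Wnt genes 0.0054 and the 39 Hox genes -0.0021. Tgfb3, a ligand gene of the TGF-beta family, was higher by 1.33 (SE 0.23). It passed when adjusted over the list alone (limma, adjusted p = 0.0387), with no adjustment across the lists. Tgfb1, another ligand gene of the list, went the other way without overlap between the groups, by -0.80 (SE 0.22), and did not pass. Among markers of other cells, the medians were -0.071 for 30 myeloid genes, -0.073 for 20 lymphocyte genes, -0.059 for 16 erythroid and megakaryocyte genes and -0.040 for 20 epithelial genes. The mean had the opposite sign to the median for cell cycle inhibitors (0.18), centrosome genes (-0.0062), osteoblast genes (0.21), adipocyte genes (0.097), chondrocyte genes (0.013) and Hox genes (0.055).

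The third question was whether the ploidy difference was the same in primary cultures as in lines and clones, since origin was partly mixed with ploidy. In the primary cultures, tetraploid I was set against diploid II and III, and in lines and clones tetraploid II and III against diploid I. H19 was lower in both, by log2 differences of -5.47 and -4.50. Rspo2 was higher in both, by 4.47 and 3.83, and Bmper was lower in both, by -3.82 and -3.15. The groups did not overlap for H19, Rspo2 or Bmper, and the last 2 were named for that reason. The same direction in both origins was therefore given in advance and does not answer the question. The median of the mitosis list was -0.10 in primary cultures and -1.53 in lines and clones. The median of the cholesterol list was 1.86 and 0.82, and that of the extracellular matrix list 0.23 and 0.36. At an adjusted p under 0.05 there were 0 probe sets in primary cultures, 0 in lines and clones and 0 for the difference between them (limma, smallest adjusted p = 0.345, 1 and 0.776). At an unadjusted p under 0.05 each of these counts lay below the 1296 given by chance. The spread in these tests came from diploid II and III and from tetraploid II and III, and the lone samples tetraploid I and diploid I were assumed to vary like them, so the counts do not show whether the ploidy difference was the same.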

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

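The tests of explanations in this part were chosen after the results were seen.

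In 6 gene lists, camera with its preset correlation called a difference between the ploidy differences of primary cultures and of lines and clones. The median difference, primary minus lines and clones, was 1.59 for interferon genes (adjusted p = 6.2e-24), 1.24 for mitosis genes (adjusted p = 9.2e-28), 1.10 for p53 targets (adjusted p = 4.5e-09), 1.07 for cholesterol genes (adjusted p = 0.000659), 0.30 for cell cycle inhibitors (adjusted p = 0.0266) and 0.11 for oxidative phosphorylation genes (adjusted p = 0.0266). None of the 6 held with an estimated correlation (adjusted p = 0.917 for each), and each origin had a lone sample of 1 ploidy, so that the values rest on single arrays. Tetraploid I alone had the highest value for 29 of 34 interferon genes and diploid I alone for 39 of 50 mitosis genes.

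Among the 9482 probe sets without a gene symbol, which entered no comparison of genes, 172 were higher and 9 lower in the tetraploid samples at an unadjusted p under 0.05 and 2-fold, or 1.81% higher. Among probe sets with a symbol 0.714% were higher in the same fit.

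H19 was lower in each tetraploid sample. The log2 difference without diploid III, the array with the narrower value range, was -5.53. The high values of diploid I and II (8.36 and 10.46) already set that result. The pattern did not rest on diploid III, but this is no separate test of its range. The differences within origins were -5.47 in primary cultures and -4.50 in lines and clones, so the recorded origin alone did not give the pattern. The gap between all tetraploid and all diploid values already set both differences, so this is no separate test of origin. Each origin also had a lone sample of 1 ploidy. Loss of the chromosome copies that express this imprinted gene would lower neighbours by about 1 on the log2 scale, and the median difference was -0.48 (SD 0.40 between genes) for the 4 bright neighbours and -0.15 (SD 0.41) for the 10 above the median of all probe sets. The 4 are few and the 10 include dim and imprinted genes, so this stays open. Tetraploidy and an unrecorded difference in culture history also stay open as hypotheses, untested by this design.

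Mitosis and spindle genes were lower in the tetraploid samples as a list, but the call did not hold with an estimated correlation (camera, adjusted p = 0.673). Diploid III had the lowest diploid mean of the list, 6.23, so a wider difference without it, a median of -0.93, was set by these values. The pattern did not rest on that array, but this is no separate test of its range. Culture origin stays open, because the median was -0.10 within primary cultures and -1.53 within lines and clones. Fewer dividing cells would lower the replication-dependent histone genes too, and more so in lines and clones, where the mitosis genes were lower by more. Of 40 such histone genes 37 were lower, with a median of -1.14, and of -0.57 without diploid III. The SE of that -1.14, 0.11, was taken over genes, which are not independent replicates, and not over cultures. Between origins the histone genes ran opposite to the mitosis genes, with -1.09 in primary cultures and -0.45 in lines and clones. Without diploid III the median in primary cultures was -0.40. Size and order thus rest on that array, and paralogs share sequence, so the histone genes do not decide and this explanation stays open.

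Cholesterol synthesis genes were higher in tetraploid I and II. The list mean of diploid III was 7.08, against 7.19 and 7.10 in diploid I and II, so the median of 1.14 without it was set by these values. The pattern did not rest on that array, but this is no separate test of its range. Culture origin stays open, because the weaker within-origin median of 0.82, in lines and clones, came from tetraploid II, a cell line. The clones, tetraploid III and diploid I, had list means of 7.14 and 7.19. Tetraploidy alone would raise tetraploid III too, where the median over the list was 0.049 above the diploid mean, against 1.92 and 1.66 in tetraploid I and II. As this is 1 array, ploidy itself was not excluded. Culture conditions are a candidate explanation that the labels do not record.

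With 10 ways to split 6 arrays into 3 and 3, no share under 0.05 can be reached. For probe sets past the adjusted threshold the real split gave 0 and the highest other 1 (limma, with 1332 probe sets at an unadjusted p under 0.05 in the real split); all 10 splits gave as many, as a real count of 0 requires, so this decides nothing. For probe sets at an unadjusted p under 0.05 and 2-fold the real split gave 284 and the highest other 890, and 2 splits gave as many. The split with 890 set tetraploid I, tetraploid II and diploid III against the rest, which points to a structure of the samples other than ploidy. For gene lists the real split gave 7 and the highest other 9, and 5 splits gave as many.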

How the results depend on the processing

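Leaving out tetraploid II together with diploid III, and estimating the correlation within lists in other settings, were chosen after seeing the data; the other alternatives were planned. The H19 values did not overlap between the groups, so leaving out replicates could not turn its direction. H19 kept its direction in all alternatives, and leaving out 1 replicate gave log2 differences from -5.53 to -4.46. H19 passed the adjusted threshold in 1 of them, without diploid II (limma, adjusted p = 0.0208), where the arrays left vary less for this gene, and over all alternatives its adjusted p ran up to 0.997. The number of probe sets past the adjusted threshold ran from 0 to 1 when 1 replicate was left out, the other case being Lgr5 without tetraploid III (limma, adjusted p = 0.00401), and was 0 in the other alternatives.

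The count at an unadjusted p under 0.05 and 2-fold was 284 and moved to 138 with the ordinary linear model, to 138 in the authors' deposited table, to 435 with array weights, to 472 over all probe sets and to 763 at 1.5-fold. More probe sets and a lower threshold account for the last 2 of these by construction; for the others the cause was not tested. Leaving out 1 replicate gave 166 to 636, and the cause was not tested. The share of higher calls was 63.4%, and it ran from 43.6% without diploid III to 75.6% over all probe sets, with 48.3% with array weights, 71.0% with the ordinary linear model and 72.3% without tetraploid II.

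The number of gene lists called was 7, and 0 with an estimated correlation and 0 with fry. Where the correlation was estimated in other settings it was 0 too, except 1 without tetraploid III. With the preset correlation it was 5 after quantile normalisation and 8 with centred arrays, with the filter on dim probe sets and with origin as a covariate. It ran from 6 to 11 with that correlation when 1 replicate was left out, with 11 without tetraploid II, and was 9 without tetraploid II and diploid III. In that setting the glycolysis list had a median of -0.21, and Egln3 was at -1.98, Pfkp at -0.76, Sqle at 0.90, Lss at 0.76, H4c17 at -0.98, Limk1 at -0.80 and Pold1 at -0.36. The median of the interferon list reversed to -0.30 without tetraploid I, the sample with the high values, and ran up to 0.89 with another replicate left out. Lists that passed only under alternatives included the NRF2 and glutathione list, lower in 7 of them, and the p53 targets, higher in 3 of them, in no case with an estimated correlation. The lymphocyte list had no gene left under the filter on dim probe sets, and the variance models do not enter camera. Named genes other than H19, Xist and Y-linked ones kept direction and side of the threshold in 1512 values under alternatives. Lgr5 crossed it in 1. None passed in the main fit, so keeping that side tests nothing. These genes were named from the same arrays, for no overlap between the groups or for a small p. Leaving out replicates cannot reverse a gene without overlap, so the kept direction is no independent evidence. Xist and Y-linked genes were given per sample only.

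The repeat numbers did not pair the samples: deviations of same-numbered samples correlated at -0.117, -0.149 and -0.337 across genes, and the highest of the 9 pairs of a tetraploid with a diploid sample was 0.307, of tetraploid III with diploid I. With the repeat number as a replicate block there were 0 probe sets past the adjusted threshold, 290 at an unadjusted p under 0.05 and 2-fold, and 6 gene lists, with the endothelial list lost (camera, adjusted p = 0.0539) and H19 at -5.17. Signal over background limits H19 in the tetraploid samples, where values of 3.75 to 3.97 lie close to the arrays' lower quartiles of 3.82 to 4.02, so its difference may be understated.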

Other observations

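The values in this part were picked out after the data were seen, and no explanation was tested for them.

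Tetraploid I had the highest value of the 6 samples for 29 of 34 interferon response genes. Ifit1 was at 10.1 in tetraploid I and at 3.83 to 6.01 in the others, and Ifi44 at 9.71 against 4.10 to 6.17. Of 32 p53 target genes, 20 were highest in tetraploid I and 17 lowest in tetraploid II. Cdkn1a, the p21 cell cycle inhibitor gene, was at 6.25 in tetraploid II and at 9.41 to 10.06 in the others.

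Eng, which encodes endoglin, was at 3.80 in tetraploid II and at 8.80 to 10.78 in the other samples. Thy1 was at 10.8 in tetraploid I, 8.56 in diploid I and 3.96 to 6.29 in the others. Lgr5, a receptor gene for R-spondins, was at 9.98 in tetraploid I, 10.14 in tetraploid II and 3.86 to 4.06 in the others. Mitosis genes had their lowest value in tetraploid II for 43 of 50 genes and their highest in diploid I for 39.

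Across probe sets, which are not independent replicates, diploid I and II correlated at 0.986 with each other. Tetraploid III correlated at 0.988 with diploid II, at 0.984 with diploid I and at 0.944 with diploid III. With tetraploid I and II, tetraploid III correlated at 0.969 and 0.961. The labels do not say whether this artificial clone was made from one of the diploid samples.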
